A study of Arabidopsis thaliana with 15 samples.

How the data were processed

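Total RNA of leaves was sequenced in 15 libraries of Arabidopsis thaliana, 3 from WT and 3 from each of 4 ubc22 subtypes (Types I to IV), made with a kit that marks no strand. The authors name the TAIR10 genome, STAR 2.4.0j, StringTie 1.0.3, HTSeq 0.6.0 and DESeq2 1.12.4 without saying which step each served. The deposited table holds 34307 loci and its unit is treated as signal, that is, normalized values. Each library's values are whole multiples of 1 step (100% within a tolerance of 1e-06), and that step is the inverse of the library's median-of-ratios size factor, so whole reads could be recovered. Recovered totals were 8865955 to 13138977 reads per library. Of the loci 260 carried no AGI code (0.136% of reads), and 1379 codes had more than 1 locus. Of 32580 AGI codes 31881 were found in the reference annotation, which gave chromosomes and gene order. All 15 columns were mapped to labels, 2 of them through a slip in the column name. Libraries were grouped by subtype as labelled. Labels share no replicate numbers between groups, so no paired test was made.

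Differences were tested with limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(normalized count + 1), for 17595 loci with a mean of at least 10 over the 15 libraries, with all libraries in 1 fit. Calls had a Benjamini-Hochberg adjusted p under 0.05, over all loci tested in a comparison. The comparisons, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The quasi-likelihood test of edgeR was planned then, and limma replaced it because the deposited unit is not counts. The minimum of 10 and the pseudocount of 1 were set during an exploratory run in which counts under other settings were seen. The named genes are UBC22, the 10 risen and 10 fallen loci with the largest log2 fold change in each subtype (adjusted p under 0.05, at least 2 CPM over the 6 libraries, groups that do not overlap), the first 5 in each direction for pairs of subtypes, and up to 4 members with the smallest p of each list. Where a group had 0 reads, a fold is a lower bound from a floor of 3 reads over the group, and with 1 to 3 reads a ratio with a 95% counting interval is given. These bounds cover counting error only.

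The chromosome shift is the median log2 fold change of the tested genes of a chromosome minus that of the other nuclear chromosomes. In values per library, a subtype library was set against the mean of all WT libraries. A WT library was set against the mean of the other WT libraries, which gives WT values a wider spread than around the mean of all WT libraries. Shifts and gene lists were tested with camera at its preset correlation of 0.01, and again with the estimated correlation. Adjusted p for lists covers 80 tests. The 22 lists held salicylic acid defence, jasmonate response, ethylene and jasmonate-ethylene defence, indole glucosinolate and camalexin synthesis, aliphatic glucosinolate synthesis, light reactions and Rubisco, chlorophyll synthesis, senescence, leaf shape, auxin early response, cell cycle, ubiquitin-conjugating enzymes, proteasome subunits, heat shock, abscisic acid and cold, flavonoids, the clock, iron deficiency, flowering, DNA methylation, root markers, and seed and embryo markers. Of 425 members 418 were in the table and 342 were tested. UBC22 was also compared between 3 WT and 12 mutant libraries with an exact permutation test. Sharing between subtypes was set against independent lists and against 50 simulated sets of unchanged groups that use the same WT libraries.

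The fit was tested on simulated data with few changed genes (67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold in each subtype). In Type I against WT it recovered 26.9% of simulated 1.5-fold changes, 74.6% of 2-fold and 97% of 4-fold changes with 6 false calls. The other subtypes gave 28.4% to 35.8%, 71.6% to 83.6% and 98.5% to 100% with 8 to 9 false calls. These shares need not hold in the data for genes that spread widely between libraries. Alternatives tried were other scalings, filters, thresholds and pseudocounts, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom, a fit of the compared groups alone, and leaving out each library in turn. Chosen after seeing the data were edgeR on recovered reads, the pseudocounts of 0.5 and 5, TMM as an alternative, centring each library per chromosome, and the singling out of Type IV replicate 3 among the libraries left out in turn. Gene families from annotation text, the division of clock genes by time of day, the tables of lists and clock genes per library, and the list of loci changed in all subtypes were also made after values had been seen. Sensitivity of list calls was first kept as medians, and was changed to adjusted p after results were known. Results for 1 withheld item were not used here.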

Results

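RNA from leaves of 21-day-old Arabidopsis thaliana plants of the Col-0 accession was sequenced in 15 libraries, 3 from WT and 3 from each of 4 subtypes of the ubc22 mutant. UBC22 encodes a ubiquitin-conjugating enzyme, one of the proteins that carry activated ubiquitin to the ligases that attach it to targets. The mutant plants were offspring of 1 parent and were sorted by the look of their leaves. Type I resembled WT, Type II had broad and round leaves, Type III had pale, long and narrow leaves, and Type IV plants were small with toothed leaf edges. The comparisons ask which genes differ between each subtype and WT, and between the subtypes. The libraries held 8865955 to 13138977 reads counted in genes, with group means from 9995578 in WT to 12010678 in Type III. The labels call the 3 libraries of a group biological replicates and do not say how many plants entered each, so p-values measure the spread between these libraries. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom within groups lay between 3.79 and 19.1. WT replicate 1 stood apart from WT replicates 2 and 3 (up to 18.6, against 3.79 between those), and Type IV replicate 3 from Type IV replicates 1 and 2 (up to 19.1, against 6.36 between those).

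UBC22 (AT5G05080) lies on chromosome 5 of the TAIR10.1 assembly, from 1498438 to 1500784 on the minus strand, and its reference transcript has 7 exons. Its normalized read count was 684.7 ± 18.8 in WT (SD, n = 3), 261 ± 39.9 in Type I, 272.1 ± 40 in Type II, 303.2 ± 14.2 in Type III and 313 ± 67.3 in Type IV. The subtypes thus held 38.1%, 39.7%, 44.3% and 45.7% of the WT level. Each of the 12 mutant libraries lay below each WT library, with a mutant mean of 287.3 ± 44.1 (exact permutation test of 3 WT against 12 mutant libraries, 2-sided p = 0.0022, the smallest that 455 splits can give). By limma the log2 fold change was -1.40 ± 0.15 in Type I (SE, adjusted p = 0.000436), -1.34 in Type II (adjusted p = 0.000127), -1.17 in Type III (adjusted p = 2.11e-05) and -1.15 in Type IV (adjusted p = 9.63e-05). The labels do not say which part of the gene the mutation affects, and gene counts do not separate its parts.

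**Figure D1:**
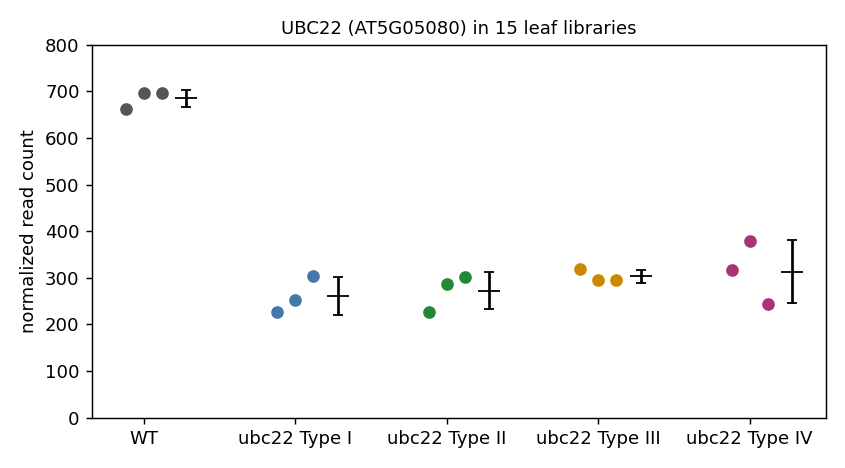
Normalized read count of UBC22 in each of the 15 libraries (points), by group, with the group mean and SD beside them (bar and whiskers, n = 3). WT libraries lie between 663 and 695.6, and the mutant libraries between 226.5 and 377.9.

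In Type I leaves ASP2, which encodes an aspartate aminotransferase, was lower, at 4.09 ± 2.58 normalized read counts against 671 ± 112 in WT (SD, n = 3). MRD1 fell by 7.43 on the log2 scale (SE 0.56, adjusted p = 6.3e-06), and AT5G24240, annotated as a phosphatidylinositol kinase of the ubiquitin family, fell by 7.04 (SE 0.58, adjusted p = 1.48e-05). The transposable element gene AT5G35935 rose from 9.31 ± 4.61 to 189.7 ± 24.4 counts (log2 fold change 4.31 ± 0.25, adjusted p = 2.03e-07). RGL1, a DELLA repressor of gibberellin responses, rose by 0.88 (adjusted p = 0.0384). NCED4, a carotenoid cleavage dioxygenase, rose by 0.72, and OEP16, a channel of the outer plastid envelope, by 0.45 (adjusted p = 0.0411 for both). In all, 13 of 17595 loci passed in Type I against WT, 8 higher and 5 lower, and 2549 had an unadjusted p under 0.05. Counts in this comparison depended on single libraries: 6 loci passed without Type I replicate 3, 8 without Type I replicate 1 or WT replicate 3, 53 without WT replicate 1 and 92 without Type I replicate 2. Leaving out a Type II or a Type III library, which changes only the shared spread, also gave 8 (without Type II replicate 2, or without Type III replicate 3). Without Type I replicate 3, RGL1 and BAG6, a calmodulin-binding cochaperone, had adjusted p = 0.316, PYD4 and NCED4 had adjusted p = 0.325, OEP16 had adjusted p = 0.216 and AT3G30122 had adjusted p = 0.126. These 6 loci also missed the threshold without WT replicate 2 (adjusted p from 0.0679 to 0.148) and without WT replicate 3 (0.135 to 0.154), all but AT3G30122 without Type I replicate 1 (0.102 to 0.202), and OEP16 without WT replicate 1 (0.0559). Scaled to library totals alone, 4 loci were higher and 7 lower, and edgeR gave 7 and 7.

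By limma 0 of 342 members of the gene lists passed over all genes in Type I and 100 had an unadjusted p under 0.05, while camera called 12 of 20 lists. Over all loci edgeR called 14 in this comparison, limma-voom 8 and DESeq2 203. The aliphatic glucosinolate genes, whose products make sulphur-rich defence compounds, lay higher, with 12 of 17 passing when adjusted over the list alone (camera adjusted p = 4.2e-11, adjusted p = 0.42 with an estimated correlation). The jasmonate response genes lay higher with a median log2 fold change of 1.13, and 13 of 20 passed adjusted over the list alone (camera adjusted p = 7.65e-09, adjusted p = 0.546 with an estimated correlation). Over this list WT replicate 3 stood apart, with a median of -1.096 against 0.45 in each of WT replicates 1 and 2. Each WT library was set against the mean of the other WT libraries. The abscisic acid and cold genes had a median of 0.42 and 6 of 19 passing adjusted over the list alone (camera adjusted p = 1.22e-05, adjusted p = 0.546 with an estimated correlation). The light reaction and Rubisco genes (median 0.23, camera adjusted p = 3.14e-05) and the flavonoid genes (median 0.61, camera adjusted p = 5.75e-05) had none passing adjusted over the list alone, and both had adjusted p = 0.546 with an estimated correlation. WT replicate 1 lay highest in WT over the flavonoid genes (0.51, against -0.17 and -0.41). The flowering genes (4 of 8 passing adjusted over the list alone, camera adjusted p = 0.00766) and the leaf shape genes (2 of 33, camera adjusted p = 0.00248) lay higher, each with adjusted p = 0.42 with an estimated correlation. The clock genes lay higher (1 of 16 adjusted over the list alone, camera adjusted p = 0.00673) and the cell cycle genes lower (0 of 27, camera adjusted p = 0.000709), each with adjusted p = 0.546 with an estimated correlation.

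The salicylic acid defence genes of Type I lay lower than in WT, with 2 of 19 passing adjusted over the list alone (camera adjusted p = 9.74e-05, adjusted p = 0.629 with an estimated correlation). That list followed WT replicate 1, whose median over the list was 1.78 above the mean of WT replicates 2 and 3 on the log2 scale. WT replicates 2 and 3, each against the mean of the other WT libraries, lay at -1.12 and -0.62. Without WT replicate 1 its adjusted p was 0.317. The ethylene and jasmonate-ethylene genes (2 of 11 higher adjusted over the list alone, camera adjusted p = 0.0329) had adjusted p = 0.546 with an estimated correlation, 0.133 without WT replicate 1, 0.181 without Type I replicate 1 and 0.099 without its 1 member on chromosome 4. The indole glucosinolate and camalexin genes (0 of 15 adjusted over the list alone, camera adjusted p = 0.0126) had adjusted p = 0.703 with an estimated correlation, 0.0507 without WT replicate 2 and 0.454 without WT replicate 3. With fry, a rotation test of gene lists, 9 of the 12 called lists of Type I were not called, and aliphatic glucosinolates, leaf shape and flowering were. The other 8 lists had adjusted p from 0.159 to 0.994. Without WT replicate 1, the senescence list was called as well (adjusted p = 0.00387).

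In Type II leaves 3 plant defensins of the jasmonate-ethylene pathway were higher than in WT. PDF1.3, on chromosome 2 and with 0 reads in the WT libraries, was at least 176-fold higher (floor of 3 reads over the group), and PDF1.2A rose by 5.45 on the log2 scale (SE 0.80, adjusted p = 0.000623). PDF1.2C had 3 reads over the WT group and a ratio of 74.1, with a 95% counting interval from 25 to 362. These defensin genes are near-identical in sequence, and their reads were not told apart further here. FLC, the MADS-box repressor of flowering, fell to 6.55 ± 1.43 counts (SD, n = 3), a log2 fold change of -3.18 (SE 0.31, adjusted p = 5.57e-05), and AP1, a floral identity gene with 0 reads in Type II, was at least 5.83-fold lower. Among the largest changes AGL19, a MADS-box promoter of flowering, rose by 3.49 (adjusted p = 0.000104). ASP2 fell by 6.99 (adjusted p = 6.79e-08) and MRD1 fell by 6.42 (adjusted p = 3.19e-05). ELIP2, an early light-induced protein, fell by 1.93, but without Type II replicate 3 its adjusted p was 0.12. It was 0.0916 without WT replicate 2 and 0.0841 without WT replicate 3.

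Chromosome 2 as a whole was higher in Type II. The median log2 fold change of its 2659 tested genes lay 0.57 ± 0.03 above that of the other nuclear chromosomes (SD over 3 libraries, camera adjusted p = 1.52e-84, and adjusted p = 1.59e-07 with an estimated correlation). Of these genes 96% had a log2 fold change above 0, 1367 rose and 0 fell. The other 4 chromosomes had shifts between -0.08 and -0.06. Their reference includes the raised chromosome 2, which by itself gives unchanged chromosomes a negative shift. In a simulation that raised chromosome 2 alone by 1.5-fold, the unchanged chromosomes lay between -0.064 and -0.051. In all, 2564 loci passed in Type II, 1793 higher and 771 lower, and 77.1% of the nuclear genes that rose lay on chromosome 2, which held 15.2% of those tested. With scaling factors taken from the other chromosomes 2233 were higher and 421 lower. Fewer passed without WT replicate 3 (1575) and without Type II replicate 3 (1702), and 1426 passed with only the libraries of both groups in the fit. With each library centred per chromosome, which removes the shift itself, 467 passed, 324 higher and 143 lower.

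**Figure D2:**
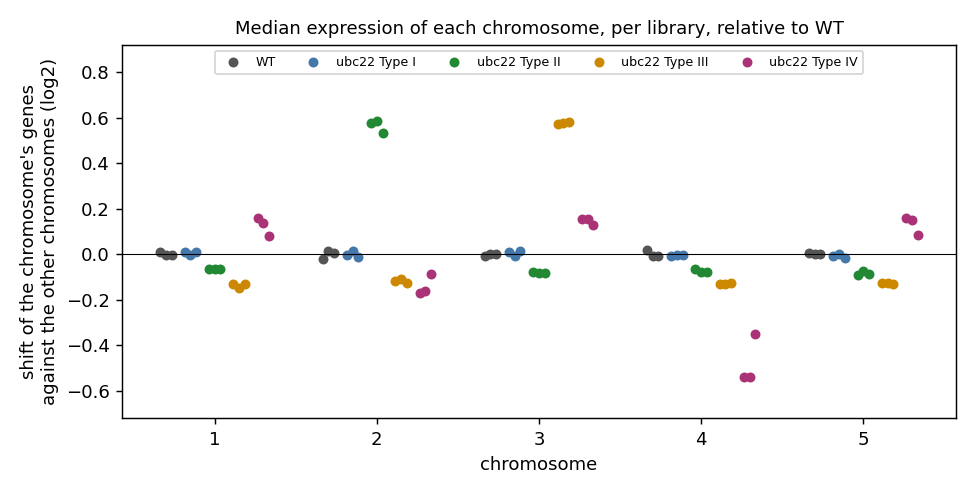
Shift of the genes of each chromosome against the other nuclear chromosomes (log2), 1 point per library, coloured by group. Subtype libraries are relative to the WT mean, and each WT library to the mean of the other WT libraries. Chromosome 2 lies between 0.531 and 0.585 in Type II, chromosome 3 between 0.571 and 0.582 in Type III, and chromosome 4 between -0.54 and -0.35 in Type IV.

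Of the 20 jasmonate response genes 8 rose in Type II and 0 fell (13 adjusted over the list alone, camera adjusted p = 7.33e-06, adjusted p = 0.546 with an estimated correlation), with WT replicate 3 the lowest of WT over this list and adjusted p = 0.0596 with fry. They included OPR3, an enzyme of jasmonate synthesis (1.59, adjusted p = 0.00795), which lies on chromosome 2. CORI3 (2.34, adjusted p = 0.0139) and the storage protein VSP2 (3.18, adjusted p = 0.0174) rose too. Their adjusted p was 0.069 and 0.0879 without WT replicate 3, and 0.0593 and 0.0712 without Type II replicate 3. Of the ethylene and jasmonate-ethylene genes 4 of 11 rose (7 adjusted over the list alone, camera adjusted p = 0.000281, adjusted p = 0.42 with an estimated correlation), among them HEL, a hevein-like protein (1.59, adjusted p = 0.00235). Of the indole glucosinolate and camalexin genes 7 of 15 rose (9 adjusted over the list alone, camera adjusted p = 4.45e-06, adjusted p = 0.546 with an estimated correlation), with WT replicate 1 the highest of WT over this list. Of the 7 risen genes, 4 lie off chromosome 2. CYP79B3, on chromosome 2, which makes indole-3-acetaldoxime from tryptophan, rose by 1.55 (adjusted p = 0.000941) and its regulator MYB34 by 1.37 (adjusted p = 0.00135). Of the aliphatic glucosinolate genes 3 of 17 rose (4 adjusted over the list alone, camera adjusted p = 0.00669, adjusted p = 0.629 with an estimated correlation, and 0.125 with fry). Of the abscisic acid and cold genes 4 of 19 rose (5 adjusted over the list alone, camera adjusted p = 0.0098, adjusted p = 0.629 with an estimated correlation), and P5CS1 of proline synthesis, on chromosome 2, rose by 1.29 (adjusted p = 0.00247). Of the 4 risen genes 2 lie off chromosome 2. The adjusted p of that list was 0.105 without WT replicate 3, 0.0782 without its members on chromosome 2 and 0.128 with fry.

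Chlorophyll synthesis genes lay lower in Type II, with 5 of 16 fallen and 2 risen (8 and 3 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.547 with an estimated correlation). CHLI1, a subunit of magnesium chelatase, fell by 0.48 (adjusted p = 0.00398), and GLK1, a regulator of chloroplast genes on chromosome 2, rose by 0.89 (adjusted p = 0.00862). Of 21 auxin early response genes 5 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.00799, adjusted p = 0.609 with an estimated correlation). GH3.6, an auxin-conjugating enzyme, fell by 0.80 (adjusted p = 0.00274), GH3.3, on chromosome 2, rose by 0.76, and the auxin list had adjusted p = 0.103 without Type II replicate 1 and 0.114 with fry. The 6 leaf shape genes that rose, of 33, included the growth-regulating factors GRF1 (0.90) and GRF3 (0.76) and the polarity gene AS1 (0.60) on chromosome 2, and ROT3, a cytochrome P450 of brassinosteroid synthesis, which rose by 1.43 (camera adjusted p = 0.148, 6 adjusted over the list alone). Only 1 of the 6 lies off chromosome 2, and 51.4% of all tested genes of that chromosome rose. None of 19 salicylic acid genes passed (camera adjusted p = 0.156, 0 adjusted over the list alone). That value was 0.00253 without WT replicate 2, 0.0295 without WT replicate 3 and 0.0186 without Type II replicate 1. Of the clock genes 3 of 16 rose, all on chromosome 2 (camera adjusted p = 0.328, 3 adjusted over the list alone). None of 27 light reaction and Rubisco genes passed (camera adjusted p = 0.132, 0 adjusted over the list alone), with adjusted p = 0.0318 without WT replicate 1, 0.0356 without Type II replicate 1 and 0.00872 without its members on chromosome 2.

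In Type III leaves genes of the circadian clock differed from WT. FKF1, a blue-light receptor of the flowering pathway that peaks in the afternoon, had 0 reads in WT and was at least 204-fold higher. PRR5, a clock repressor of the afternoon, rose to 782.2 ± 31.8 counts (SD, n = 3), a log2 fold change of 6.10 (SE 0.48, adjusted p = 2.7e-07), and GRP7, a glycine-rich protein of the evening, rose by 4.32 (SE 0.18, adjusted p = 1.54e-09). CCA1, the MYB-like factor that peaks at dawn, fell from 2933 ± 321 to 406.5 ± 28.9 counts (log2 fold change -2.85, SE 0.12, adjusted p = 1.54e-09), and RVE8, of the same family, fell by 2.55 (adjusted p = 2.41e-08). All 16 tested clock genes passed, 10 higher and 6 lower (10 and 6 adjusted over the list alone), and camera, which sets the list against other genes in 1 direction, did not call it (adjusted p = 0.0583, 0.0487 without WT replicate 1 and 0.00706 without its members on chromosome 3). The labels give no hour of harvest.

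**Figure D3:**
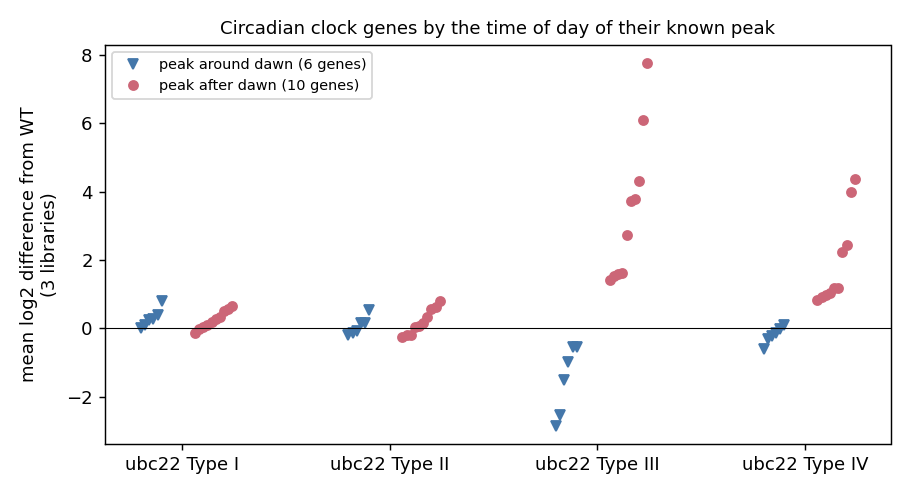
Mean log2 difference from WT (3 libraries) of the 16 tested clock genes in each subtype, 1 point per gene, by the textbook time of day of the gene's peak. The 10 genes that peak after dawn have a median of 3.23 in Type III and 1.17 in Type IV, and the 6 that peak around dawn have medians of -1.26 and -0.17. FKF1 had 0 reads in WT, so the height of its points depends on the pseudocount.

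Chromosome 3 as a whole was higher in Type III. Its 3533 tested genes lay 0.58 above the other nuclear chromosomes (SD 0.005 over 3 libraries, camera adjusted p = 7.72e-25, and adjusted p = 2.95e-09 with an estimated correlation), with 80.4% above 0, 1998 risen and 206 fallen. The other 4 chromosomes, whose reference includes the raised chromosome 3, had shifts between -0.13 and -0.12. Among 8379 loci past the threshold, 4226 were higher and 4153 lower, and with scaling factors taken from the other chromosomes 5163 were higher and 3302 lower. Chromosome 3 held 47.4% of the nuclear genes that rose. Large rises beside clock genes included those of AT1G56300, a DnaJ-domain chaperone (7.08, adjusted p = 1.58e-08), and MIOX4, a myo-inositol oxygenase (6.03, adjusted p = 7.07e-05). NIC2, a nicotinamidase, rose by 5.58 (adjusted p = 4.46e-07) and BCAT-2, a branched-chain amino acid transaminase, by 5.23 (adjusted p = 7.1e-07). COR27, a cold and clock regulated gene, had 2 reads over the WT group and a ratio of 118 (95% counting interval 32.3 to 978). ASP2 fell by 6.97 (adjusted p = 8.21e-09), the wall-associated kinase WAK3 fell by 4.80 (adjusted p = 5.43e-05) and PCC1, a pathogen and circadian controlled gene, fell by 4.95 (adjusted p = 0.000111).

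The flavonoid and anthocyanin genes fell in Type III, the libraries with the shifted clock genes: 14 of 17 fell and 2 rose (14 and 2 adjusted over the list alone, camera adjusted p = 9.31e-06, adjusted p = 0.452 with an estimated correlation). LDOX, which makes anthocyanidins, fell by 3.61 (SE 0.33, adjusted p = 1.12e-06), and the glucosyltransferase UGT78D2 fell by 1.93 (adjusted p = 4.27e-07). Aliphatic glucosinolate genes fell in 13 of 17 cases (14 adjusted over the list alone, camera adjusted p = 2.41e-05, adjusted p = 0.546 with an estimated correlation), with MAM3, an enzyme of chain elongation, at -2.18 (adjusted p = 1.42e-07) and the regulator MYB29 at -1.47 (adjusted p = 3.77e-05). Indole glucosinolate and camalexin genes fell in 12 of 15 cases (12 adjusted over the list alone, camera adjusted p = 0.00312, adjusted p = 0.629 with an estimated correlation). Over this list the medians of WT replicates 1, 2 and 3 were 0.865, -0.131 and -0.503, and those of the Type III libraries -1.369, -0.494 and -1.143. Of the salicylic acid defence genes 11 of 19 fell and 0 rose (12 adjusted over the list alone, camera adjusted p = 0.000784, adjusted p = 0.689 with an estimated correlation, and 0.0505 with fry). PR1, the pathogenesis-related marker of this pathway, was at 15.3 ± 16.2 counts against 1221 ± 1540 in WT (log2 fold change -6.19 ± 0.96, adjusted p = 0.000115). Over this list the medians of the Type III libraries lay at -2.61, -1.37 and -1.49, and those of WT at 1.78, -1.12 and -0.62, with WT replicate 1 the highest. For this list and the indole list, WT medians are against the mean of the other WT libraries, which widens their spread beside the Type III medians.

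Cell cycle genes fell in Type III, 15 of 27 against 1 risen (15 and 1 adjusted over the list alone, camera adjusted p = 0.000307, adjusted p = 0.546 with an estimated correlation). They included the replication helicase subunit MCM2 (at -1.35, adjusted p = 9.9e-05) and the sliding clamp PCNA1 (at -1.36, adjusted p = 0.000272). Abscisic acid and cold genes rose in 13 of 19 cases (14 adjusted over the list alone, camera adjusted p = 0.000367, adjusted p = 0.546 with an estimated correlation), with the dehydrin COR47 up by 2.14 (adjusted p = 2.75e-05) and NCED3, of abscisic acid synthesis and on chromosome 3, up by 2.03 (adjusted p = 5.29e-05). Of 24 ubiquitin-conjugating enzyme genes other than UBC22, 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.00766, adjusted p = 0.546 with an estimated correlation). UBC2 rose by 1.32 (adjusted p = 4.3e-07), UBC5 by 1.07 (adjusted p = 0.000105), and UBC18 fell by 0.76 (adjusted p = 0.000888). Flowering genes rose in 6 of 8 cases (6 adjusted over the list alone, camera adjusted p = 0.0241, adjusted p = 0.42 with an estimated correlation), among them the MADS-box genes SOC1 (1.81, adjusted p = 5.72e-07) and FUL (2.23, adjusted p = 3.5e-06). Of 21 auxin genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0498, adjusted p = 0.701 with an estimated correlation). GH3.5, an auxin-conjugating enzyme, rose by 1.44 (adjusted p = 2.09e-05), and the list had adjusted p = 0.181 without WT replicate 1, 0.116 without Type III replicate 1 and 0.111 without its members on chromosome 3.

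Other lists moved both ways in Type III. Of the senescence genes 6 rose and 4 fell among 12 (6 and 4 adjusted over the list alone, camera adjusted p = 0.232). SEN1, a gene of dark and sugar starvation, rose by 4.45 (adjusted p = 4.27e-05) and SAG21 fell by 2.83 (adjusted p = 3.38e-05). Of 27 light reaction and Rubisco genes 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.972), with a median of 0.02 and a mean of -0.07. The Rubisco small subunit gene RBCS2B fell by 1.42 (adjusted p = 2.19e-06), while the antenna genes LHCA1 and LHCA2, both on chromosome 3, rose by 0.94 and 0.91. The RBCS genes are near-identical in sequence as well. In the pale leaves of Type III, 9 of 16 chlorophyll synthesis genes fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0854, and 0.0424 without Type III replicate 3). CAO, which makes chlorophyll b, fell by 0.72 (adjusted p = 0.000167). Of 33 leaf shape genes 12 rose and 7 fell (12 and 7 adjusted over the list alone, camera adjusted p = 0.53). TCP10, a regulator that limits leaf cell division, fell by 1.21 (adjusted p = 3.92e-06), and LNG2, a gene of longitudinal leaf growth on chromosome 3, rose by 1.22 (adjusted p = 2.69e-05).

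Among the remaining lists of Type III, 5 of 14 proteasome subunit genes rose (5 adjusted over the list alone, camera adjusted p = 0.0917), 3 of them on chromosome 3. Of 6 iron deficiency genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.984). Among those NAS4, a nicotianamine synthase, fell by 2.46 (adjusted p = 1.86e-06) and BTS, an iron-sensing ligase on chromosome 3, rose by 0.87 (adjusted p = 2.98e-06). Of 9 heat shock genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.973), with HSP15.7 up by 1.54 (adjusted p = 0.000659). Of 13 DNA methylation genes 4 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.777), with a median of 0.09 and a mean of -0.04. DDM1, a chromatin remodeller needed for DNA methylation, fell by 1.16 (adjusted p = 1.19e-06), the methyltransferase CMT3 fell by 0.92 (adjusted p = 5.01e-06), and DCL3, a Dicer-like enzyme on chromosome 3, rose by 0.82 (adjusted p = 2.09e-05). Of 20 jasmonate genes 2 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.783), and of 11 ethylene genes 2 rose (1 adjusted over the list alone, camera adjusted p = 0.954). None of the 11 root markers or the 14 seed and embryo markers reached the expression minimum, and their highest group means were 14.2 and 8.78 counts.

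**Figure D4:**
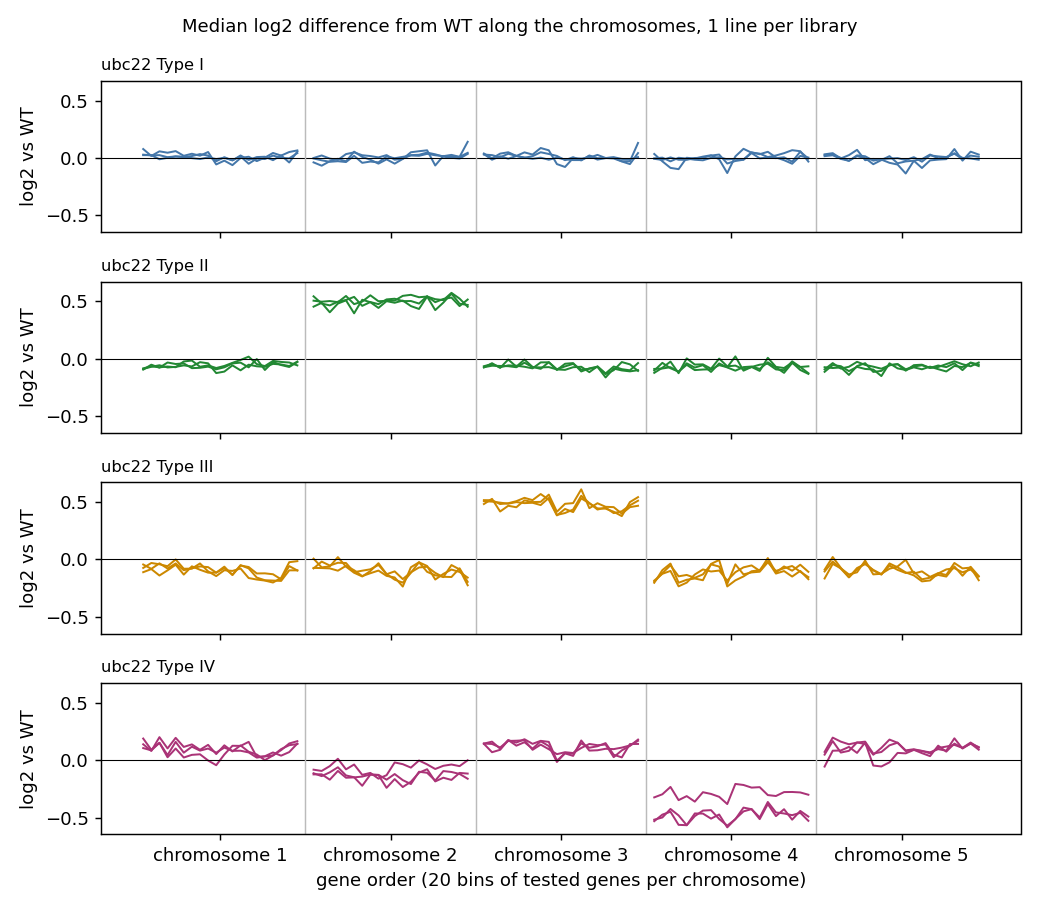
Median log2 difference from WT in 20 bins of gene order per nuclear chromosome, 1 line per library, for the 4 subtypes. Chromosome 2 of Type II, chromosome 3 of Type III and chromosome 4 of Type IV are displaced over their whole length. Pooled over libraries and in 10 bins per chromosome, which the figure does not draw, the 3 chromosomes lie between 0.54 and 0.591, between 0.532 and 0.613, and between -0.543 and -0.439 against the other chromosomes.

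In Type IV leaves the flavonoid and anthocyanin genes were lower and several clock genes higher than in WT. LDOX fell by 2.64 (SE 0.33, adjusted p = 7.04e-05), the anthocyanin glucosyltransferase UGT75C1 fell by 2.43 (adjusted p = 0.000146), both on chromosome 4, and 13 of 17 genes of the list fell against 1 risen (13 and 1 adjusted over the list alone, camera adjusted p = 0.000275, adjusted p = 0.546 with an estimated correlation). FKF1, with 0 reads in WT, was at least 19.6-fold higher, GRP7 rose by 2.44 (SE 0.18, adjusted p = 2.04e-06), PRR5 by 4.00 (adjusted p = 5.15e-05) and GI, a clock and flowering gene of the afternoon, by 2.23 (adjusted p = 2.75e-05). Of 16 clock genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.452 with an estimated correlation). BCAT-2 rose by 4.87 (adjusted p = 8.94e-06), and the glyoxalase gene GLYI4 by 4.76 (adjusted p = 5.8e-05).

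Chromosome 4 as a whole was lower in Type IV. Its 2637 tested genes lay at -0.47 ± 0.11 against the other nuclear chromosomes (SD over 3 libraries, camera adjusted p = 9.89e-27, and adjusted p = 0.00174 with an estimated correlation), and 81 rose while 1290 fell. By library the shift was -0.54, -0.539 and, in Type IV replicate 3, -0.35. Chromosome 2 lay at -0.14 ± 0.05 (camera adjusted p = 0.00845, adjusted p = 0.0697 with an estimated correlation), and chromosomes 1, 3 and 5 between 0.12 and 0.15. The reference of each of these includes the lowered chromosome 4, which raises their values. In all 5815 loci passed, 2816 higher and 2999 lower, and with scaling factors taken from the other chromosomes 2227 were higher and 3666 lower. Of the nuclear genes that fell 43.1% lay on chromosome 4, which held 15.1% of those tested. Without Type IV replicate 3, singled out after its distance had been seen, 5725 passed, and 4061 without Type IV replicate 1. Genes with large falls included ACD6, a regulator of defence and cell death on chromosome 4 (-2.65, adjusted p = 0.00296), ELIP2, on the same chromosome (-3.07, adjusted p = 0.000768), and ASP2 (-6.76, adjusted p = 7.21e-08).

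Abscisic acid and cold genes rose in 7 of 19 cases in Type IV (11 adjusted over the list alone, camera adjusted p = 0.000367, adjusted p = 0.546 with an estimated correlation), with the dehydrin RAB18 up by 1.37 (adjusted p = 0.000154) and RD22 by 0.99 (adjusted p = 0.000435). Of 24 ubiquitin-conjugating enzyme genes 10 rose and 2 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.547 with an estimated correlation), and the list had adjusted p = 0.0582 without WT replicate 1. UBC2 rose by 0.67 (adjusted p = 0.00051) and UBC27 by 0.50 (adjusted p = 0.000702). Of 14 proteasome subunit genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0176, adjusted p = 0.546 with an estimated correlation), with RPT3, an ATPase of the regulatory particle, up by 0.88 (adjusted p = 3.35e-05). That list had adjusted p = 0.0985 without Type IV replicate 3. Flowering genes rose in 3 of 8 cases (4 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.42 with an estimated correlation, and 0.0545 without WT replicate 2). FUL rose by 1.55 (adjusted p = 0.000273), FLC by 1.41 (adjusted p = 0.0032) and SOC1 by 0.84 (adjusted p = 0.00114). Since FLC represses flowering, the call of the list gives no direction of flowering. Of 17 aliphatic glucosinolate genes 5 fell, 3 of them on chromosome 4 (5 adjusted over the list alone, camera adjusted p = 0.00591, adjusted p = 0.629 with an estimated correlation). That list had adjusted p = 0.061 without its members on chromosome 4 and 0.0727 with fry.

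In the toothed leaves of Type IV, 10 of 33 leaf shape genes rose and 5 fell (13 and 5 adjusted over the list alone, camera adjusted p = 0.149, and 0.0276 without its members on chromosome 4). TCP10 fell by 0.86 (adjusted p = 0.000251), and SPL3, a phase change regulator, rose by 0.87 (adjusted p = 0.0004). Of 27 cell cycle genes 6 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.209), with MCM3 at -1.04 (adjusted p = 0.00259). Of 27 light reaction and Rubisco genes 7 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.269): RBCS1B fell by 1.22 (adjusted p = 0.00118), and the antenna gene LHCB5, on chromosome 4, fell by 0.71 (adjusted p = 0.000511). Of 16 chlorophyll synthesis genes 4 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.173, and 0.0382 without Type IV replicate 2). Only 2 of the 4 fallen genes lie off chromosome 4, and 48.9% of all tested genes of that chromosome fell. Of 19 salicylic acid genes 2 rose (0 adjusted over the list alone, camera adjusted p = 0.16, with 0.000921 without WT replicate 1 and 0.0209 without Type IV replicate 2). Those were PAD4 and SAG101, lipase-like partners in defence, at adjusted p = 0.0305 and 0.0322, and without Type IV replicate 3 their adjusted p was 0.13 and 0.109. They also missed the threshold without WT replicate 2 (0.139 and 0.159), WT replicate 3 (0.0776 and 0.0971) and Type IV replicate 1 (0.0679 and 0.0564). Of 20 jasmonate genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.115, and 0.00819 without Type IV replicate 3 or 0.0353 without WT replicate 2). The risen genes VSP1, OPR3 and MYC2 had adjusted p = 0.0753, 0.0843 and 0.0859 without WT replicate 3, and 0.0757, 0.0769 and 0.093 without Type IV replicate 1. Without Type IV replicate 2 it was 0.0774 for OPR3 and 0.0772 for MYC2, and MYC2 had 0.0523 without WT replicate 2.

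Type II differed from Type I in PDF1.2A and PDF1.3, in FLC and in chromosome 2. PDF1.2A was higher in Type II by 5.62 on the log2 scale (adjusted p = 0.000625), and PDF1.3 by 6.45 (adjusted p = 0.000205). FLC was lower, at -2.68 (adjusted p = 0.000314), as was the cytochrome P450 gene CYP706A3, at -2.17 (adjusted p = 0.00149). In all 2510 loci passed, 1663 higher and 847 lower in Type II, with 84.2% of the higher nuclear genes on chromosome 2. The split was 1983 and 473 with scaling factors from the other chromosomes, 2147 and 377 with library totals, and 161 and 228 with each library centred per chromosome. Without Type I replicate 3, 1537 passed, and without Type I replicate 1, 1650.

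Type III differed from Type I in FKF1, PRR5 and MIOX4, which were higher. FKF1 had 1 read over the Type I group and a ratio of 634 (95% counting interval 113 to 25100). PRR5 was higher by 5.45 (adjusted p = 9.24e-07), and MIOX4 by 6.48 (adjusted p = 4.48e-05). UF3GT, an anthocyanin glycosyltransferase, was lower, at -4.68 (adjusted p = 7.83e-07), as was the stearoyl desaturase gene S-ACP-DES6, at -5.26 (adjusted p = 5.99e-06). In all 7317 loci passed, 3751 higher and 3566 lower in Type III, or 4727 and 2757 with scaling factors from the other chromosomes.

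Type IV differed from Type I in LDOX, on chromosome 4 and lower, at -3.32 (adjusted p = 1.84e-05), and in UF3GT, lower, at -3.45 (adjusted p = 5.49e-05). BCAT-2 was higher by 4.03 (adjusted p = 4.44e-05), and MIOX4 by 4.37 (adjusted p = 0.00266). In all 4899 loci passed, 2239 higher and 2660 lower in Type IV, and 3191 passed without Type IV replicate 1. The split was 1614 and 3205 with scaling factors from the other chromosomes, and 3483 and 1792 with library totals, which moved the median log2 fold change of all genes to 0.12.

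Type III differed from Type II in PR1 and PDF1.3, both on chromosome 2. PR1 was lower in Type III, at -7.31 (adjusted p = 2.15e-05), and PDF1.3, with 0 reads in Type III, was at least 199-fold lower. AT1G56300 was higher by 6.49 (adjusted p = 3.46e-08), and GDPD2, a glycerophosphodiester phosphodiesterase, by 6.15 (adjusted p = 4.04e-05). PHE1, a MADS-box gene known from seed development, had 3 reads over the Type II group and a ratio of 80.5 (95% counting interval 27.2 to 393). In all 9082 loci passed, 4448 higher and 4634 lower in Type III. The split was 5649 and 3675 with scaling factors from chromosomes other than 3, where the median of all genes moved to 0.10, and 3394 and 5723 with library totals, where it moved to -0.14.

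Type IV differed from Type II in FLC, higher by 4.59 (SE 0.31, adjusted p = 1.07e-06), and in GDPD2, higher by 5.13 (adjusted p = 0.000376). PDF1.2A was lower, at -6.91 (adjusted p = 2.19e-05), and DIN11, a dark-induced oxygenase, at -4.22 (adjusted p = 3.35e-05). In all 7362 loci passed, 3433 higher and 3929 lower in Type IV, or 2473 and 4696 with scaling factors from chromosomes other than 2, and 2007 and 2097 with each library centred per chromosome. Type IV differed from Type III in PR1, higher by 7.17 (adjusted p = 0.00011), and in WAK3, higher by 5.15 (adjusted p = 0.000103). FKF1 was lower in Type IV than in Type III, at -3.40 (adjusted p = 0.000143), as was NIC2, at -3.23 (adjusted p = 0.000189). In all 6091 loci passed, 2680 higher and 3411 lower in Type IV. The split was 2063 and 4086 with scaling factors from chromosomes other than 3, 4085 and 2169 with library totals, where the median of all genes moved to 0.12, and 1307 and 1824 with each library centred per chromosome.

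Across the subtypes 9 loci passed in the same direction in all 4 comparisons with WT, and they are named here after their values were seen. ASP2, MRD1, AT5G24240 and UBC22 fell. AT5G35935, BAG6, OEP16, AT1G30160 and CUFF.2165.1, a locus assembled from reads with 0 reads in WT and 39.8 to 45.7 counts in the subtypes, rose. The mutant plants came from 1 parent. Another difference carried by that line cannot be told apart from an effect of the ubc22 mutation in comparisons with WT. ASP2, AT5G24240 and AT5G35935 lie on chromosome 5, as UBC22 does. Types III and IV shared 1949 higher and 1818 lower loci, against 676.4 and 707.9 for independent lists of those sizes, and 101 loci changed in opposite directions. Across genes, which are not independent replicates, their log2 fold changes correlated with r = 0.66, and unchanged groups simulated against the same WT libraries gave 0.516. The covariance was 0.32 against a simulated 0.0284, and on chromosomes 1 and 5 alone 0.316 against 0.0285. Types II and III shared 483 higher and 335 lower loci (430.6 and 182 for independent lists, 476 opposite). Their covariance was 0.0586 against a simulated 0.0284, and r was 0.154 against a simulated 0.514. Types II and IV shared 346 and 272 (287 and 131.4, 320 opposite). Their covariance was 0.068 against 0.0285, and r was 0.252 against 0.516. On chromosomes 1 and 5 alone Types II and III shared 99 higher and 258 lower loci (39.1 and 131.3 for independent lists, 73 opposite). Types II and IV shared 109 and 139 there (48.2 and 44.6, 45 opposite), and r stayed below the simulated values (0.242 against 0.513, and 0.351 against 0.515). Of the 13 loci of Type I, 11 passed in the same direction in Type II, 12 in Type III and 10 in Type IV. Across genes Type I correlated with these at r = 0.471, 0.418 and 0.401, below the simulated 0.509, 0.51 and 0.512, with covariances of 0.0798, 0.127 and 0.0866 against simulated 0.0285, 0.0284 and 0.0286. With 3 WT libraries the controls could not be divided, so part of the sharing may come from the shared WT libraries. The simulation drew each gene independently. It holds no departure common to many genes of a library, such as that of WT replicate 1, so its covariances may be too low. The excess of covariance over the simulated values thus cannot be read as shared change alone. Nor does an r below the simulated values show less sharing. The simulated groups hold no changes, and changes in 1 subtype alone lower r.

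Over all 5 groups 12190 of 17595 loci (69.3%) differed by limma. The first principal component held 46.1% of the variance and separated Type III (66.5 to 75.4) and Type IV (2.1 to 30.7) from WT, Type I and Type II (-50.5 to -15.6), and the second held 14.3%. Type IV replicate 3 lay at 2.1 on the first component, against 26.7 and 30.7 for the other Type IV libraries, and at 52.5 on the second, against 40.2 and 35.3.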

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

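The tests of copy number for chromosomes 2, 3 and 4 were chosen only after the shifts had been seen, while those of GC content, gene length and mixing were written before their results were known. The values of single libraries set beside the mixing test were chosen after they had been seen.

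Between subtypes, whole chromosomes differed in 9 of the 30 tests of pairs by more than 0.3 on the log2 scale. Against Type I, chromosome 2 lay at 0.57 in Type II (camera adjusted p = 1.31e-86, adjusted p = 1.05e-07 with an estimated correlation), chromosome 3 at 0.573 in Type III (1.21e-29 and 9.16e-10) and chromosome 4 at -0.468 in Type IV (7.55e-32 and 0.000468). Against Type II, chromosome 2 lay at -0.675 in Type III (1.56e-30 and 9.77e-06) and at -0.7 in Type IV (4.05e-47 and 1.38e-06), chromosome 3 at 0.677 in Type III (8.14e-32 and 9.16e-10), and chromosome 4 at -0.421 in Type IV (4.56e-15 and 0.00549). Between Types III and II, chromosomes 2 and 3 each lie in the other's reference, which enlarges both shifts. Against Type III, Type IV had chromosome 3 at -0.453 (1.36e-25 and 1.32e-09) and chromosome 4 at -0.371 (1.37e-14 and 0.00588).

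In Type II the genes of chromosome 2, and in Type III those of chromosome 3, were higher over the whole chromosome. After regression on GC content and gene length, known for 99.8% of genes, the smaller shift was 0.566, which argues against either trend as the whole cause. The lowest of the 6 libraries lay at 0.531 and the highest at 0.585, and 3 copies in place of 2 would give 0.585, so an added copy of the chromosome in most cells is a candidate explanation. That value was known when the test was chosen, and DNA was not analysed here. A difference between the subtypes that acts on a whole chromosome without a change in copy number stays open and untested.

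In Type IV the genes of chromosome 4 were lower over the whole chromosome, and chromosome 2 lay at -0.257, -0.238 and -0.142 against chromosomes 1, 3 and 5 in the 3 libraries. The shift was -0.478 after regression on GC content and length, which argues against either trend as the whole cause, and its lowest library lay at -0.54, far from the -1 that loss of 1 of 2 copies in all cells would give if expression followed copy number. With 2 copies of chromosome 4 beside 3 of chromosomes 1, 3 and 5 the value would be -0.585. Of 3 libraries 2 lay near it (-0.586 and -0.581, against -0.373 in Type IV replicate 3). In those 2 libraries chromosome 2 lay at -0.257 and -0.238, between what 3 copies and 2 copies of it would give. This possible explanation thus leaves chromosome 2 unaccounted for, and it cannot be told apart from others with 3 libraries. Over 3476 genes called without it, Type IV replicate 3 showed 0.71 of the change of the other libraries, and 0.64 for chromosome 4, a difference of 0.07. Replicates 1 and 2, each treated alike, gave 1.03 and 0.915. Genes chosen by their change in the other libraries by themselves give a lower ratio in the library left out. The values of replicates 1 and 2 do not measure this effect, since replicate 3 was among their other libraries. The difference of 0.07 therefore does not decide on mixing. Replicate 3 lay nearer to WT in PRR5 (2.666 against 5.036 and 4.285) and PRR7 (0.557 against 1.226 and 1.328), as in GI and FKF1. In ELF3, PRR9, LUX and TOC1 it lay between the others. Mixing would add reads at the same share for every gene, and whether 1 share gives these differing values was not tested. The clock genes therefore do not decide on mixing. RNA mixed with that of plants or cells without the Type IV state may contribute to the smaller shift of replicate 3. UBC22 was lowest in replicate 3 (243.5 against 317.6 and 377.9, and 684.7 in WT), and ASP2 averaged 5.4 in Type IV against 671 in WT. These values argue against RNA of WT plants at such a share. Mixing with RNA like that of WT would not by itself place this library further from WT than the others, as on the second principal component (52.5 against 40.2 and 35.3), in GRP7, 1 of 9 risen clock genes and the only one so placed (2.673 against 2.517 and 2.115), and in the proteasome list (0.304 against 0.163 and 0.14), and the subtype itself remains an open, untested explanation.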

How the results depend on the processing

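Centring per chromosome, edgeR on recovered reads, the pseudocounts of 0.5 and 5, TMM and the singling out of Type IV replicate 3 among the libraries left out in turn were chosen only after the data had been seen. UBC22 and the shifts of chromosome 2 in Type II, 3 in Type III and 4 in Type IV kept their direction and their side of the threshold under each alternative run for them. With an estimated correlation 4 smaller shifts against WT lost the call: chromosome 2 in Type IV (adjusted p = 0.0697) and Type III (0.152), and chromosome 4 in Type II (0.287) and Type III (0.389). So did 3 against Type I: chromosome 4 in Type II (0.253), and chromosomes 2 (0.0878) and 4 (0.311) in Type III. In Types II and III the reference of these chromosomes includes the raised one, which by itself gives unchanged chromosomes a negative shift. Chromosome 2 in Type I, not called, went from 0.004 to -0.003 without Type I replicate 2. Of 6219 values of 317 named gene results, 5801 kept both, 415 lost the call and 3 reversed, all after centring per chromosome, which removes the chromosome's own shift: RCCR in Type IV (0.046), RPN1a in Type II (-0.027) and PBB1 in Type III (-0.154). In Type I against WT 25 loci passed with no filter, 3 at 10 CPM or more, 7 at adjusted p under 0.01, 8 with limma-voom and 203 with DESeq2; the cause of the last was not tested. At an absolute log2 fold change of at least 1 the counts were 378 (Type II), 2383 (Type III) and 1106 (Type IV) against WT, 310, 2053 and 924 for Types II, III and IV against Type I, 2787 and 1526 for Types III and IV against Type II, and 1181 for Type IV against Type III. At adjusted p under 0.01 they were 1107 and 3284 for Types II and IV against WT, 1126 and 2473 for the same types against Type I, 4679 for Type IV against Type II and 3378 for Type IV against Type III. With the 2 compared groups alone Type II against WT gave 1426. Centred per chromosome, Type II gave 467 against WT and 389 against Type I, and Type IV 4104 against Type II and 3131 against Type III. Without genes on shifted chromosomes the ratio of observed to independent sharing was 21 for Types I and II, 2.08 for Types II and III and 2.52 for Types II and IV. Leaving out 1 library, counts ranged from 6 (without Type I replicate 3) to 92 (without Type I replicate 2) in Type I and from 1575 (without WT replicate 3) to 3104 in Type II against WT, and from 4061 (without Type IV replicate 1) to 5925 in Type IV against WT. They ranged from 1537 (without Type I replicate 3) to 2888 for Types II and I, and from 3191 (without Type IV replicate 1) to 5351 for Types IV and I. Of the lists, 0 in Type I, 0 in Type II, 0 in Type III and 0 in Type IV were called with an estimated correlation, and fry called 3 in Type I and 4 in Type II. With that correlation the adjusted p was, in Type I, 0.629 for salicylic acid, 0.703 for indole glucosinolates, 0.42 for aliphatic glucosinolates, leaf shape and flowering, and 0.546 for the other called lists. In Type II it was 0.546 for jasmonate and indole glucosinolates, 0.42 for ethylene, 0.547 for chlorophyll, 0.609 for auxin, and 0.629 for aliphatic glucosinolates and abscisic acid. In Type III it was 0.689 for salicylic acid, 0.629 for indole glucosinolates, 0.701 for auxin, 0.452 for flavonoids, 0.42 for flowering and 0.546 for the other called lists. In Type IV it was 0.629 for aliphatic glucosinolates, 0.547 for ubiquitin-conjugating enzymes, 0.452 for the clock, 0.42 for flowering and 0.546 for the other called lists. Calls lost with fry were those of Type I for salicylic acid (0.332), jasmonate (0.0834), ethylene (0.148), indole glucosinolates (0.418), light reactions (0.0652), cell cycle (0.102), abscisic acid (0.073), flavonoids and clock (0.0644 each), of Type II for jasmonate (0.0596), aliphatic glucosinolates (0.125), auxin (0.114) and abscisic acid (0.128), of Type III for salicylic acid (0.0505), and of Type IV for aliphatic glucosinolates (0.0727). It gained flowering in Type II (0.00286), chlorophyll (0.0353), senescence (0.025), proteasome (0.011), clock (0.000106) and DNA methylation (0.0356) in Type III, and leaf shape in Type IV (0.0443). TMM gained the clock in Type III (0.0495). Without members on the chromosome with the largest shift of a comparison, which in Type I was only -0.013 and not called, ethylene in Type I (0.099), abscisic acid in Type II (0.0782), auxin in Type III (0.111) and aliphatic glucosinolates in Type IV (0.061) were lost, and light reactions (0.00872), proteasome (0.0188) and flowering (0.0223) in Type II, clock in Type III (0.00706) and leaf shape in Type IV (0.0276) were gained. Leaving out 1 library, adjusted p in Type I ranged from 3.61e-09 to 0.317 (salicylic acid), 0.00321 to 0.181 (ethylene), 9.8e-05 to 0.454 (indole glucosinolates) and 0.00387 to 0.682 (senescence). In Type II it ranged from 0.00253 to 0.828 (salicylic acid), 0.0318 to 0.397 (light reactions), 0.000921 to 0.103 (auxin) and 0.00089 to 0.105 (abscisic acid), and in Type III from 0.0424 to 0.136 (chlorophyll), 0.0201 to 0.181 (auxin) and 0.0487 to 0.0602 (clock). In Type IV it ranged from 0.000921 to 0.948 (salicylic acid), 0.00819 to 0.488 (jasmonate), 0.0382 to 0.706 (chlorophyll), 0.0227 to 0.0582 (ubiquitin-conjugating enzymes), 0.00699 to 0.0985 (proteasome) and 0.0239 to 0.0545 (flowering). The causes of these ranges were not tested. A separate RLE scaling was not run, since the deposited scaling is already median-of-ratios, and the test over 5 groups has no alternative with 2 groups or a fold threshold. In simulations with few changed genes (67 at 1.5-fold in each subtype), 26.9% to 35.8% of the 1.5-fold changes were recovered. Where many loci change, the adjusted threshold is less strict, so these shares do not carry over to Types II to IV. Nor need simulated shares hold in Type I, where 0 of 20 jasmonate genes passed over all genes at a median log2 fold change of 1.13. In the data 51.4% of the tested genes of chromosome 2 rose in Type II, and 56.6% of those of chromosome 3 in Type III. Small changes in single genes could still be missed.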

Other observations

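The division of gene families and the tests of the harvest hour were chosen only after results had been seen. Over all 17595 tested loci 1793 rose and 771 fell in Type II, 4226 and 4153 in Type III, and 2816 and 2999 in Type IV. In Type II, 16 of 37 tested genes encoded in the chloroplast genome rose and 0 fell (median 1.08, camera adjusted p = 1.91e-08, adjusted p = 0.82 with an estimated correlation). Their share of all reads was 0.0661%, 0.041% and 0.03% in the Type II libraries and 0.0214%, 0.0258% and 0.021% in WT. Type I replicate 1 (0.035%) and Type IV replicate 3 (0.0315%) lay above the lowest Type II library, and Type II replicate 1, the highest, also had the highest mitochondrial share (0.0205%). Ribosomal protein genes, 305 tested, lay lower in Type II with 26 fallen and 14 risen (median -0.23, camera adjusted p = 1.47e-05), and in Type III with 106 fallen and 44 risen (camera adjusted p = 0.0122), each with adjusted p = 0.82 with an estimated correlation. Histone genes fell in 6 of 40 cases in Type II and 1 rose (camera adjusted p = 0.00474, adjusted p = 0.82 with an estimated correlation).

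Glutathione S-transferase genes, whose products conjugate glutathione, rose in 7 of 28 cases in Type II and 0 fell (camera adjusted p = 0.00507), with a median log2 fold change of 0.425 over all and 0.145 off chromosome 2. In Type III 11 fell and 1 rose (camera adjusted p = 0.0162). Each had adjusted p = 0.82 with an estimated correlation, and the difference itself was not tested. Immune receptor genes of the TIR-NBS-LRR class fell in 26 of 67 cases in Type III and 6 rose (camera adjusted p = 0.00507, adjusted p = 0.82 with an estimated correlation). In Type I camera also called ribosomal protein genes lower (median -0.108, camera adjusted p = 8.39e-05), histone (0.00507) and TIR-NBS-LRR genes (0.00245) lower, and glutathione S-transferase (0.00507), cytochrome P450 (0.000834) and UDP-glycosyltransferase genes (0.000922) higher. In each of these 0 members passed, with adjusted p = 0.82 with an estimated correlation. Pentatricopeptide repeat genes, which process organelle RNA, fell in 26 of 189 cases in Type IV and 3 rose (camera adjusted p = 0.00983, adjusted p = 0.82 with an estimated correlation). Falls were no more frequent among them than over all loci (2999 of 17595), and rises were rarer (2816 over all loci).

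Genes off the shifted chromosome also changed, 1175 in Type II, 6152 in Type III and 4426 in Type IV. With scaling factors from the other chromosomes 86.8% of these calls remained in Type III and 87.1% in Type IV, which argues against library scaling as their whole cause, and 70.2% remained in Type II, where it cannot be told apart for the rest. In clock genes, the median of those that peak after dawn exceeded that of those that peak around dawn by 4.481 in Type III and 1.345 in Type IV. A later hour of harvest than WT is a candidate explanation that cannot be told apart from an effect of the subtype on the clock, since the labels give no hour. Per library the contrast was 4.534, 4.604 and 3.877 in Type III, 1.703, 1.379 and 1.432 in Type IV, and between -0.197 and 0.35 in the other groups.

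Among the 10 splits of each pair of groups, too few for a share under 0.05, 1 gave as many calls, the real one. Against WT the real count and the highest other were 13 and 1 in Type I, 2564 and 21 in Type II, 8379 and 0 in Type III, and 5815 and 1 in Type IV. They were 2510 and 0 for Types II and I, 7317 and 0 for Types III and I, 4899 and 0 for Types IV and I, 9082 and 0 for Types III and II, 7362 and 0 for Types IV and II, and 6091 and 1 for Types IV and III. Over the 5 groups, 1 of 100 splits, the real one, gave 12190 loci, and the highest other gave 3956, so a chance division of the libraries is unlikely there. Splits that mix subtypes widen the spread within groups, which by itself lowers their counts. A condition shared by the libraries of a group, such as the hour of harvest, is not addressed.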
